A study of Arabidopsis thaliana with 24 samples.

How the data were processed

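RNA from root meristems of dexamethasone-treated seedlings was hybridised to Affymetrix whole-transcript arrays, with 3 arrays at each of 8 times. Per the labels' protocols, seeds were kept in the cold for 2 days and seedlings were grown at 22 °C, and 100 ng of RNA with an integrity number of at least 8.0 was used. The deposited values are log2 expression values made with RMA, per the submitters' processing notes, which covers background correction, quantile normalization and summary per probe set. The RMA software version and the array's genome build are not given in the sources used here. RMA forces arrays to similar distributions, which can hide a shift of most genes in one direction. The values carry no detection calls, and they ran from 0.154 to 13.2.

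The table held 38408 probe sets. The platform annotation paired 16746 of them with 1 gene and 758 with several, and 20904 were unnamed here. Probe sets with 1 gene were averaged per gene on the log2 scale, which gave 16554 genes, 163 of them with several probe sets. Symbols were updated through the TAIR10.1 RefSeq table, where 16601 probe sets matched, and no coordinates were used beyond the order of genes. Many genes of the cytokinin, auxin transport and xylem lists had no probe set with a single name and were not analysed here.

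Groups were the 8 times, taken from the sample titles. One linear model with 8 group means was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), so that all times shared one estimate of the spread. The spread was not equal: arrays had residual SDs from 0.197 to 0.215 at 0 h and from 0.153 to 0.165 at 6 h. The shared estimate can therefore understate the error of comparisons with 0 h. Each time was compared with 0 h, the mean of 4, 5 and 6 h with the mean of 0.5, 1 and 2 h, and all 7 changes from 0 h in a moderated F test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry, wherever at least 2 members were measured. Of 25 lists with 284 genes fixed before the data were examined, 9 had at least 2 measured genes, 6 had 1 and 10 had none. A further 21 lists with 357 measured genes were composed from the annotated genes before any comparison was computed.

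The genes named are DOF2.1 and LHW, the 12 largest rises and 8 largest falls at 1 h, at 6 h and in late against early among called genes whose arrays did not overlap between the sides, and 3 rises and 2 falls at other times. Up to 4 called members of each fixed list and up to 2 that were not called were added. The text gives part of these.

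The limma step was tested on simulated data for the 6 h comparison, with 200 of 16554 genes changed in each of 5 draws. It recovered 35.2% of genes changed by 0.5 in log2, 86.3% of those changed by 1 and 99.7% of those changed by 2, with 4.54% of calls false. The simulated noise was independent between arrays and genes and had the same spread at all times. The real arrays differ in this, so these shares need not hold for the real calls. Shared 0 h arrays were examined in 100 simulations with no change at any time. The alternatives tried were another variance model, array weights, median centring, a second quantile normalization, the replicate number as a block, no dim genes, the brightest probe set per gene, a log2 change of at least 1, fits of the 6 arrays compared, 0.5 h as the reference, and leaving out each array. All probe sets by ID, and a fit without the third repeat of 0 to 2 h, were added after the data were seen. For single genes at 1 to 6 h, the ranges over all alternatives include the fit with 0.5 h as the reference. That fit compares with 0.5 h and not with 0 h, so a high adjusted p there does not weaken a call against 0 h.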

Results

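Root meristems of Arabidopsis thaliana seedlings were profiled on 24 arrays over a time course of dexamethasone treatment. The Col-0 seedlings carried TMO5 and LHW, a pair of basic helix-loop-helix transcription factors that act together in vascular cell proliferation. Each was fused to the glucocorticoid receptor domain and driven by the RPS5A promoter, which is active in dividing cells. Dexamethasone moves such fusion proteins into the nucleus. Seedlings aged 4 days were transferred to medium with the steroid, and 3 arrays were measured at each of 0, 0.5, 1, 2, 3, 4, 5 and 6 h. Array medians lay between 3.86 and 4.01 on the log2 scale, and the number of arrays limits the precision of every value below. Arrays of seedlings transferred without the steroid were not analysed here, so each comparison with 0 h holds the transfer, the steroid and the elapsed time together. The labels do not say whether the repeats came from separate cultures, and p-values then measure only the spread between these arrays.

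The first principal component of the gene values held 18.8% of the variance. It rose with time up to 3 h, where arrays lay between 7.69 and 17.6, and changed little after. Repeats 1 and 2 at 0 h lay at -27.2 and -21.5 on it and the arrays of 6 h between 11 and 13.8. Repeat 3 lay further along than the mean of the others at the early times, by 19.2 at 0 h, 10.4 at 0.5 h, 11.4 at 1 h, 13.1 at 2 h and 9.7 at 3 h, and by 0.0695 at 6 h. Without array 3 of 0, 0.5, 1 and 2 h, a fit added after the data were seen called 62 genes at 1 h and 1204 at 6 h, against 78 and 686 in all arrays, and 43 of the 78 and 586 of the 686 kept their call and direction.

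**Figure D1:**
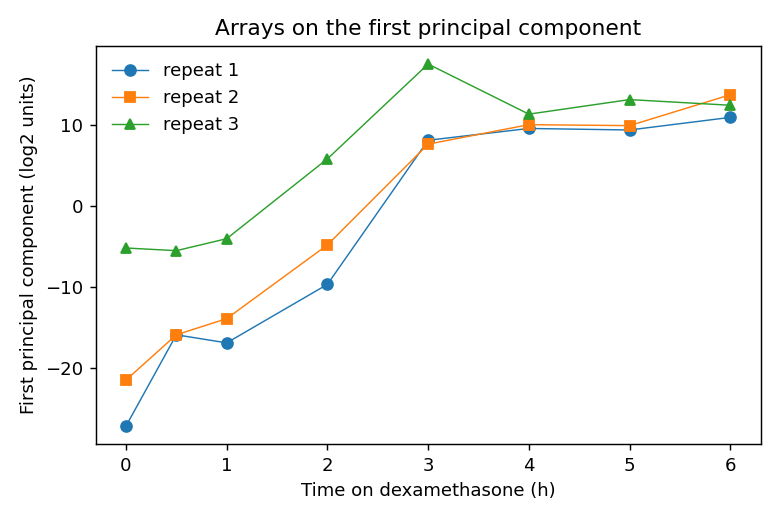
Position of each array on the first principal component in log2 units (vertical axis) against hours on dexamethasone (horizontal axis). Lines join arrays of the same repeat number, and the labels do not say what these numbers share. Repeat 3 at 0 h lay at -5.16, and repeats 1 and 2 at -27.2 and -21.5.

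The genes that the study introduced or named came first. DOF2.1 (AT2G28510), a DOF family transcription factor gene named in the title of the series, had a mean log2 value of 6.32 ± 0.27 (SD, n = 3) at 0 h, 7.42 ± 0.21 at 2 h and 7.42 ± 0.09 at 6 h. Its log2 change from 0 h was 0.12 at 0.5 h, where limma gave an adjusted p of 0.904, and 1.11 at 2 h, with an adjusted p of 3.28e-04. The change stayed between 0.94 and 1.16 from 2 to 6 h. At 1 h DOF2.1 was 0.68 above 0 h with a limma adjusted p of 0.043, and this call was lost after median centring (adjusted p = 0.0558), with array weights (adjusted p = 0.136), without array 1 or 2 of 0 h (adjusted p = 0.234 and 0.0595) and without array 2 or 3 of 1 h (adjusted p = 0.126 and 0.186). The call at 1 h was lost in 8 of 15 alternatives, 4 of them leaving out 1 array. Over all alternatives, the fit against 0.5 h included, the adjusted p ran from 0.00874 to 0.272. LHW (AT2G27230) was not called against 0 h at any time by limma, with log2 changes from -0.36 at 1 h to -0.02 at 5 h. Its values may hold RNA of the introduced copy as well as of the plant's own gene, and the 2 were not separated. TMO5 had no probe set with a single gene name and was not analysed here.

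**Figure D2:**
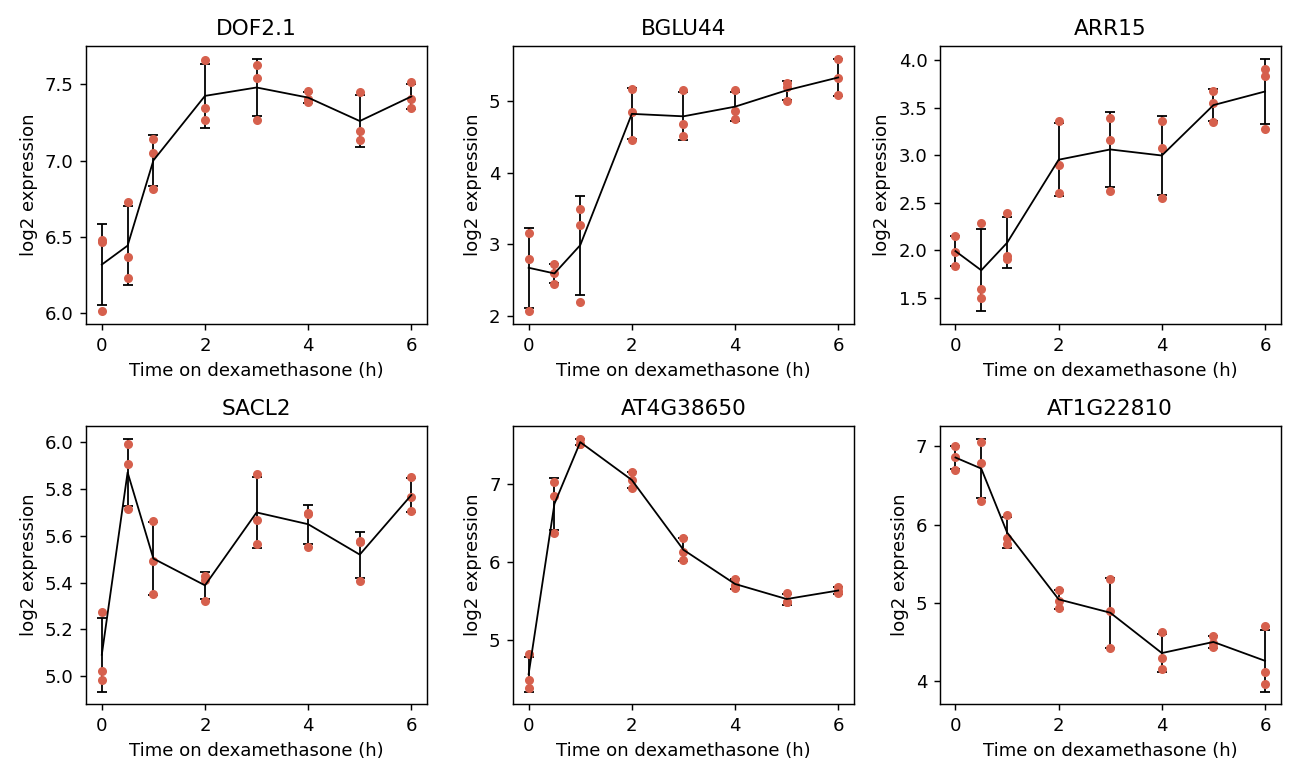
Log2 expression (vertical axis) of 6 genes against hours on dexamethasone (horizontal axis), with points for single arrays and lines with bars for the mean and SD of 3 arrays. DOF2.1 had a mean of 6.32 at 0 h and 7.42 at 6 h, and AT4G38650 was highest at 1 h, with a mean of 7.54.

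The earliest time asked which genes responded first. At 0.5 h the largest rise was that of AT4G38650, a glycosyl hydrolase family 10 gene, by 2.18 ± 0.13 (SE) in log2 (limma adjusted p = 5.03e-09). AT1G20530 rose by 1.43 and MYBC1 (AT2G40970), a MYB-like transcription factor gene, by 1.17. SACL2 (AT5G50010) and SACL1 (AT5G09460), bHLH genes related to SAC51, rose by 0.78 and 0.49. AT3G57950 fell by 1.69 and AT4G39830, of the ascorbate oxidase family, fell by 1.15. In all, 24 genes rose and 13 fell among 16554 tested with limma, and 17 and 14 after each array was centred on its median. The count of 37 was 17 without array 2 of 0.5 h and 64 without array 3 of 0 h. The call of SACL1 had an adjusted p of 0.0451 and was lost in 10 of 14 alternatives (adjusted p from 0.031 to 0.247 over all), among them those without array 1 of 0 h and without each 0.5 h array. The TMO5/LHW module is a list of bHLH genes of the complex and of its SAC51-like antagonists, with ACL5 added. It had 5 of 13 members measured, and 2 of them rose. It lay higher than other genes in camera (adjusted p = 1.9e-04, and adjusted p = 0.00458 with an estimated correlation). A list test at 0.5 h was not among those planned, which were for 1 h, 6 h and late against early.

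At 1 h AT4G38650 reached its highest level, 7.54 ± 0.04 (SD, n = 3) against 4.57 ± 0.23 at 0 h, a log2 change of 2.97 (limma adjusted p = 1.29e-11). AT2G43870 and AT3G59850, pectin lyase-like genes, rose by 1.26 and 1.12. The other large rises included AT5G39080, an HXXXD acyltransferase gene (1.64), MYBC1 (1.33), ROXY1, a glutaredoxin gene (1.30), and ATSBT5.2, a subtilase gene (1.27). AT4G39830 fell by 1.15, AT1G23160, a GH3 family gene, fell by 1.09, TRM25 fell by 1.02 and AT1G22810, an AP2/ERF family transcription factor gene, fell by 0.96. The call of AT1G22810 at 1 h had an adjusted p of 0.049 and was lost without any one of the 6 arrays compared (adjusted p from 0.0618 to 0.177, and 0.0162 to 0.259 over all alternatives). That of AT1G23160 was lost without array 1 or 2 of 0 h (adjusted p = 0.128 and 0.085) and array 2 or 3 of 1 h (0.121 and 0.0516), and that of ROXY1 without array 2 or 3 of 0 h (0.0776 and 0.0566) and array 1 of 1 h (0.0954), with 0.000713 to 0.128 and 4.5e-04 to 0.927 over all alternatives. These ranges hold the fit with 0.5 h as the reference, which compares 1 h with 0.5 h. In total 54 genes rose and 24 fell. The count of 78 was 48, 43 and 124 without array 1, 2 and 3 of 0 h, 49 without array 3 of 1 h, and 51 with array weights.

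Of the 9 fixed lists with at least 2 measured members, 2 lay higher at 1 h in camera. These were the TMO5/LHW module (mean change 0.25, adjusted p = 0.0157, and adjusted p = 0.0464 with an estimated correlation) and published targets of the complex (mean change 0.50, adjusted p = 0.0172, and adjusted p = 0.0464 with an estimated correlation). None of the 5 measured module genes was called over all genes, and 3 rose and 1 fell adjusted over the list alone. The target list had 2 measured members, DOF2.1 and BGLU44 (AT3G18080), a beta-glucosidase gene, and DOF2.1 alone was called. Because the study chose DOF2.1, this list is not independent evidence. Type-A response regulators, auxin response, phloem, G2/M and S phase genes were not called at 1 h, with mean changes of 0.10, 0.11, 0.36, -0.01 and 0.09. These means rest on few genes, such as OPS and CLE45 for phloem, AUR1 and AUR2 for G2/M, and PRL and ICU2 for S phase. Across all fixed lists 36 of 284 genes were measured, so the means do not speak for whole programmes. The module call was lost with the brightest probe set per gene (mean change 0.16, adjusted p = 0.173) and without array 2 of 1 h (adjusted p = 0.0571), with 0.0103 to 0.173 over all alternatives, and the call of the targets without array 2 of 0 h (0.0962) and array 1 or 3 of 1 h (0.0722 and 0.119, and 0.00356 to 0.119 over all alternatives).

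At 2 h BGLU44 joined the largest rises, with a mean of 4.82 ± 0.36 (SD, n = 3) against 2.67 ± 0.56 at 0 h and a log2 change of 2.15 (limma adjusted p = 2.82e-04). AT4G38650 and AT5G39080 rose by 2.49 and 1.64. AT3G12900, an oxygenase gene of coumarin synthesis, fell by 2.49 with an adjusted p of 0.0469, and AT2G41730 fell by 2.21. The call of AT3G12900 was lost without any one of the 6 arrays compared (adjusted p from 0.0566 to 0.218, and 0.0363 to 0.898 over all alternatives), and that of AT2G41730 without array 1 of 2 h (adjusted p = 0.0654, and 0.00812 to 0.0714). The ranges over all alternatives again hold the comparison with 0.5 h. At 2 h 83 genes rose and 78 fell. With each array centred on its median, the numbers were 64 and 109. The count of 161 was 103 and 275 without array 1 and 3 of 0 h, and 105 without array 1 of 2 h.

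From 3 to 5 h, AT5G38940, a germin-like gene, led the rises, with log2 changes of 2.80, 2.75 and 2.58. BGLU44 rose by 2.11, 2.25 and 2.48 at these times. ARR15 (AT1G74890), a type-A response regulator gene induced by cytokinin, rose by 1.07 at 3 h (limma adjusted p = 0.022), 1.01 at 4 h and 1.54 at 5 h. AT1G54950 rose by 2.12 at 3 h, AT5G59680, a receptor kinase gene, by 1.73 at 4 h and AT4G11393, a defensin-like gene, by 2.16 at 5 h. AT1G22810 fell by 1.98, 2.49 and 2.35, and AT2G41730 fell by 1.61, 2.49 and 2.02. EXPA7 and EXPA18, expansin genes of root hair cells, rose by 0.77 and 0.96 at 3 h. SACL2 rose at 3, 4 and 5 h by 0.61, 0.56 and 0.43. RCA, encoding Rubisco activase, rose by 0.68 at 3 h, 0.57 at 4 h and 0.56 at 5 h.

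Several of these calls lay near the threshold and were lost when 1 array of either time was left out, with the change in the same direction. It lay between 0.91 and 1.15 for ARR15 at 3 h, between 1.16 and 1.99 for AT5G59680 at 4 h and between 0.48 and 0.62 for RCA at 4 h where the call was lost. At 3 h the calls of EXPA18 (without any array but array 3 of 0 h, adjusted p from 0.0528 to 0.13), EXPA7 (array 1 or 2 of 0 h, array 1 or 3 of 3 h, 0.0679 to 0.22), ARR15 (array 1 or 2 of 0 h, array 1 or 2 of 3 h, 0.0543 to 0.0909), AT2G41730 (array 1 or 3 of 0 h, array 2 or 3 of 3 h, 0.108 to 0.175) and RCA (array 3 of 3 h, 0.0724) were lost. At 4 h those of ARR15 (any array but array 2 of 4 h, 0.0604 to 0.16), AT5G59680 (any array but array 3 of 0 h, 0.0568 to 0.244) and RCA (array 1 or 2 of either time, 0.0524 to 0.136) were lost. At 5 h those of SACL2 (array 1 or 2 of 0 h, array 1 or 3 of 5 h, 0.11 to 0.146), RCA (array 1 or 2 of either time, 0.0508 to 0.142) and AT2G41730 (array 1 of 0 h, array 3 of 5 h, 0.0502 and 0.0708) were lost. Over all alternatives, the fit against 0.5 h included, the adjusted p of these calls reached from 4.17e-05, for EXPA18, to 0.308, for RCA at 4 h.

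The numbers that rose and fell were 386 and 193 at 3 h, 294 and 170 at 4 h, and 346 and 205 at 5 h. The majority turned under median centring: 246 rose and 406 fell at 3 h, 181 and 264 at 4 h, and 247 and 338 at 5 h. It did not turn under a second quantile normalization: 339 rose and 223 fell at 3 h, 270 and 180 at 4 h, and 326 and 234 at 5 h. Without array 1, 2 and 3 of 0 h the counts were 198, 264 and 1174 at 3 h, 193, 244 and 996 at 4 h, and 220, 283 and 1023 at 5 h. Without array 1, 2 and 3 of the time itself they were 383, 374 and 195 at 3 h, 285, 230 and 190 at 4 h, and 319, 284 and 249 at 5 h.

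**Figure D3:**
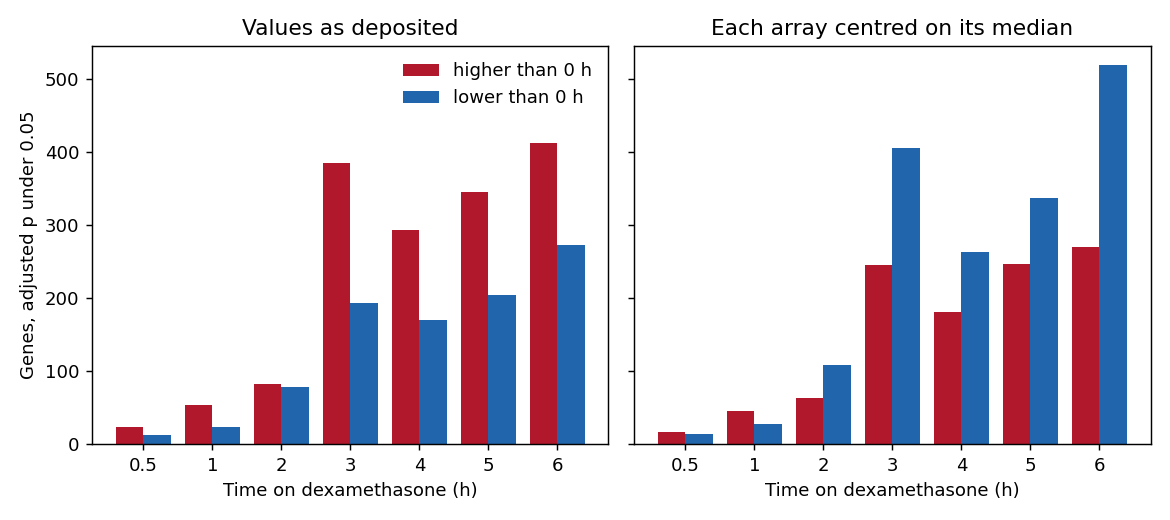
Number of genes (vertical axis) above and below the 0 h arrays at each time in hours (horizontal axis), by limma with an adjusted p under 0.05, from the values as deposited (left) and after each array was centred on its median (right). At 6 h the bars show 413 higher and 273 lower on the left, and 271 higher and 520 lower on the right.

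At 6 h, the last time, BGLU44 had the largest rise among called genes whose arrays did not overlap. Its mean was 5.33 ± 0.26 (SD, n = 3) and its log2 change 2.66 ± 0.28 (SE, limma adjusted p = 1.55e-05). AT5G38940 rose by 2.41, AT4G11393 by 2.14 and ARR15 by 1.68. The neighbouring bHLH genes AT5G51780 and AT5G51790 rose by 1.65 and 1.57. MSRB6, a methionine sulfoxide reductase gene, rose by 1.53, MT1B, a metallothionein gene, by 1.62, AT3G50300, an acyltransferase gene, by 1.52, and AT4G20450, a receptor kinase gene, by 1.51. AT5G26300 and AT4G29905 rose by 1.63 and 1.52. AT1G22810 fell by 2.59 (limma adjusted p = 9.93e-07), from 6.86 ± 0.15 to 4.26 ± 0.39. ATGSTF13, a glutathione S-transferase gene, fell by 1.96, AT3G12900 fell by 2.12 and AT2G43620, of the chitinase family, fell by 2.02. AT1G76640, a calmodulin-like gene, fell by 1.96, AT2G41730 fell by 1.92 and AT1G13480 fell by 1.74. Without single arrays the calls of AT3G12900 (any of the 6 compared, adjusted p from 0.0536 to 0.226), MT1B (any but array 3 of 0 h, 0.0729 to 0.179), AT5G26300 (array 1 or 2 of 0 h, array 1 or 3 of 6 h, 0.0782 to 0.141), AT4G20450 (array 1 or 2 of 0 h, array 2 or 3 of 6 h, 0.0589 to 0.127), AT2G41730 (array 1 of 0 h, array 3 of 6 h, 0.0542 and 0.0851) and AT2G43620 (array 1 of 0 h, 0.0596) were lost. Over all alternatives, the fit against 0.5 h included, the adjusted p of these calls reached from 1.25e-04, for AT4G20450, to 0.866, for AT3G12900.

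At 6 h 413 genes rose and 273 fell. After median centring the numbers were 271 and 520, a majority of falls, and after a second quantile normalization 368 and 306, a majority of rises. The count of 686 was 317, 410 and 1129 without array 1, 2 and 3 of 0 h, and 411, 339 and 383 without array 1, 2 and 3 of 6 h.

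Among the fixed lists at 6 h, 4 lay higher in camera and 1 of them, the published targets, did so with an estimated correlation. Both measured targets, DOF2.1 and BGLU44, rose (adjusted p = 1.19e-06, and adjusted p = 6.4e-04 with an estimated correlation), with the limit named above for DOF2.1. In the TMO5/LHW module 2 of 5 genes rose, SACL2 by 0.68 and SACL1 by 0.43, while T5L2 and T5L3 had changes of 0.13 and -0.02 (adjusted p = 0.0213, and adjusted p = 0.0792 with an estimated correlation). The module call was also lost without the dimmest 25% of genes (adjusted p = 0.0532) and with the brightest probe set per gene (adjusted p = 0.111), with 0.0203 to 0.111 over all alternatives. Adjusted over the list alone, 2 rose. Of the type-A response regulators only ARR15 and RR16 were measured. ARR15 rose and RR16, with a change of 0.28, was not called (adjusted p of the list = 0.0143, and adjusted p = 0.101 with an estimated correlation). In the epidermis and root hair list, EXPA7 and EXPA18 had changes of 0.61 and 0.81, neither called over all genes and both called adjusted over the list alone (adjusted p = 0.0143, and adjusted p = 0.124 with an estimated correlation). Vascular DOF genes other than DOF2.1 were not called: PEAR2 had a change of 0.30 and DOF2.2 of -0.05. WES1, an auxin-induced GH3 gene, rose by 0.71, alone among 8 measured auxin response genes, and the list was not called (adjusted p = 0.432). The G2/M genes AUR1 and AUR2, encoding Aurora kinases, had changes of 0.07 and 0.10, and the S phase genes PRL and ICU2 had changes of 0.10 and 0.00. The call of SACL1 was lost without array 1 of 0 h (adjusted p = 0.128) and each 6 h array (0.0515 to 0.0646), and that of WES1 without any array but array 3 of 0 h (0.0902 to 0.226), with 0.0122 to 0.875 and 0.0118 to 0.299 over all alternatives. The shoot marker RCA rose by 0.78, and the stem cell marker BBM had a change of -0.01.

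The late times (4, 5 and 6 h) were set against the early times (0.5, 1 and 2 h) to compare transferred seedlings with each other, without the 0 h arrays. AT4G11393 was higher by 2.08, AT5G38940 by 1.99, BGLU44 by 1.67 and ARR15 by 1.13 (limma adjusted p of ARR15 = 6.33e-05). AT3G18450, a PLAC8 family gene, rose by 1.29, AT3G45700, a nitrate transporter family gene, by 1.22, MSRB6 by 1.09 and AT2G38380, a peroxidase gene, by 0.98. AT1G22810 fell by 1.51, AT4G38650 fell by 1.49, ATGSTF13 fell by 1.37 and AT5G04120 fell by 1.31. AT4G22214, a defensin-like gene, fell by 1.03, AT1G14550, a peroxidase gene, fell by 1.00 and ASPGB1, an asparaginase gene, fell by 0.88. DOF2.1 was higher by 0.41 (adjusted p = 0.00536).

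In this comparison 727 genes rose and 431 fell, and 617 and 696 did so after median centring. The published targets lay higher in camera (adjusted p = 1.05e-04, and adjusted p = 0.00396 with an estimated correlation), as did the root hair expansins (adjusted p = 0.0125, and adjusted p = 0.196 with an estimated correlation) and the type-A response regulators (adjusted p = 0.0493, and adjusted p = 0.197 with an estimated correlation). Of the response regulators only ARR15 and RR16 were measured. RR16 changed by 0.01, so ARR15 alone carried the shift of that list. The TMO5/LHW module had a mean change of -0.04 and was not called. Within it LHW was higher by 0.21 with a limma adjusted p of 0.0425, a call lost after median centring (adjusted p = 0.0688) and without any one array except array 1 of 0.5 h, array 2 of 1 h and arrays 1 and 3 of 4 h, with an adjusted p from 0.0113 to 0.127 over all alternatives. The call of the response regulators was lost without the dimmest 25% of genes (adjusted p = 0.106) and without array 1 or 2 of 0.5 h, 2 or 3 of 1 h, 1 or 2 of 2 h, 3 of 4 h, 1 or 3 of 5 h and 1 of 6 h, with an adjusted p from 0.0522 to 0.0953, and 0.0137 to 0.197 over all alternatives.

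Over the whole course, the moderated F test of limma called 745 genes. From 1 to 6 h, 25 genes rose and 14 fell at every time. Of neighbouring times, 3 h against 2 h gave 2 genes higher and 1 lower by limma, with 1463 at an unadjusted p under 0.05. Between 1 h and 6 h, 175 genes were higher at 6 h and 98 lower, and 117 and 151 after median centring. That count of 273 was 157 and 165 without array 1 and 2 of 1 h, and 161, 114 and 121 without array 1, 2 and 3 of 6 h. Both comparisons with 0 h called 33 genes as rising at 1 h and 6 h and 17 as falling, where independent lists would share 1.35 and 0.396. Across genes, which are not independent replicates, the changes at 1 h and 6 h had a correlation of 0.512, and unchanged groups simulated against one set of control arrays gave 0.501. The covariance was 0.0307 against a simulated 0.0159. For 3 h and 6 h the correlation was 0.784, against a simulated 0.501, the covariance 0.0608 against a simulated 0.0159, and the shared calls 230 rising and 108 falling, where independent lists would share 9.63 and 3.18. In 100 simulations with no change, limma called 0 genes in both comparisons for either pair of times. That simulation leaves out the effects and the independent lists leave out the shared arrays. The 3 control arrays cannot be split into parts of 2, so part of these overlaps may come from the shared 0 h arrays.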

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

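The test of 6 h against 1 h was added after the data were seen, and the tests of whether the 0 h arrays alone stand apart after the late and early counts had been seen. The slopes with treated arrays in the 0 h place and the component without 0 h repeat 3 were also chosen after the slope and the gaps had been seen; the other tests were chosen before their results were seen. A test of the difference between 6 h and 1 h singled out 15 of the genes named at those times. AT4G38650 (-1.90), AT3G59850 (-0.86), AT1G20530 (-0.75) and AT2G43870 (-0.73) were lower at 6 h than at 1 h in log2, having risen at 1 h. AT1G22810 (-1.64), ATGSTF13 (-1.61) and AT1G76640 (-1.53) were also lower at 6 h than at 1 h, and of these AT1G22810 alone was called at 1 h. AT4G11393 (2.56), BGLU44 (2.34), AT5G38940 (1.78), ARR15 (1.59), AT1G23160 (1.54), MSRB6 (1.51), AT4G29905 (1.13) and AT5G51790 (0.83) were higher at 6 h. The limma adjusted p of these differences ran from 6.71e-08 for AT4G38650 to 0.0379 for AT5G38940. Without single arrays of the 2 times, 5 of these differences lost their call: AT5G38940 (any but array 3 of 1 h, adjusted p from 0.051 to 0.166), AT1G76640 (any but array 3 of 1 h, 0.0654 to 0.127), AT1G20530 (any but array 2 of 1 h, 0.0819 to 0.145), AT5G51790 (array 1 of 1 h, array 2 or 3 of 6 h, 0.0756 to 0.0898) and AT4G29905 (array 2 of 1 h or of 6 h, 0.0686 and 0.0868). Over all alternatives the adjusted p of these 5 ran from 0.00172, for AT1G76640, to 0.166. DOF2.1 differed by 0.42 between the times, which was not past the threshold (adjusted p = 0.186).

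Signal also appeared in probe sets outside the comparisons of genes. Among 20904 probe sets with no gene name here, 354 were higher and 144 lower at 6 h than at 0 h by limma over all probe sets. The same unnamed probe set had their largest rise at 1 h and at 6 h, by 3.73 and 2.79 in log2. The largest rises among the named genes were 2.97, for AT4G38650 at 1 h, and 2.66, for BGLU44 at 6 h.

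Repeat 3 of 0, 0.5, 1 and 2 h lay nearer to the later arrays on the first principal component than repeats 1 and 2. A treated sample in place of 0 h repeat 3 was tested on 69 genes that changed at 0.5 to 2 h in repeats 1 and 2. Their change in repeat 3 had a slope of 0.606, with a 95% range over genes of 0.44 to 0.749. The slope passed 0.5, the bound set beforehand against a treated sample, but the range reached below it. Repeat 3 arrays of 3, 4, 5 and 6 h, put in the 0 h place, gave 0.059, 0.128, 0.125 and 0.136. Repeats 1 and 2, which chose the genes, gave at most 0.155. These values argue against a sample treated for 3 to 6 h there. Arrays of 0.5, 1 and 2 h are part of the early mean. Their slopes cancel within a repeat and cannot decide for shorter treatment. On a first component computed without the 0 h repeat 3 array, repeat 3 still lay 10.6, 11.6 and 13.3 further along at 0.5, 1 and 2 h. Repeats 1 and 2 were at most 4.98 apart there. The 0 h repeat 3 array, whatever it held, is thus not the source of the whole pattern. A trend with signal intensity cannot be told apart: cyclic loess left 0.923 of the gap, between 0.866 and 0.976 at single times, but it moved values by a median of at most 0.0454 in log2 per array, where repeat 3 differed from the others by a median of 0.165. A difference in growth or harvest between repeats, or a partly mixed 0 h sample, remains possible and was not tested.

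From 3 h on, 464 to 686 genes differed from the 0 h arrays, which every such comparison shares. If only the 0 h arrays stood apart, the genes called at 6 h should not differ between 4 to 5 h and 0.5 to 2 h, which use neither the 0 h nor the 6 h arrays. The median difference was 0.364 for the 413 genes that rose, between 0.257 and 0.434 in single repeats, and -0.199 for the 273 that fell, between -0.219 and -0.174. This argues against the 0 h arrays as the only source. The fusion proteins, the transfer and the time of day stay open as possible sources, since arrays without the steroid were not analysed here.

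Other groupings of the arrays were counted for each comparison. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split was the 1 with the most genes at every time: 37 at 0.5 h against 2 in the highest other split, 78 against 7 at 1 h, 161 against 0 at 2 h, 579 against 4 at 3 h, 464 against 1 at 4 h, 551 against 0 at 5 h and 686 against 1 at 6 h. For late against early, 1 of 100 groupings of the 18 arrays, the real one, gave 1158 genes, and the highest other gave 23. For the F test, 1 of 100 groupings of the 24 arrays, the real one, gave 745 genes, and the highest other gave 7. A share of 1 in 100 is the lowest that such a count can give. Regrouping mixes times within a group, which widens the spread and can lower the other counts. It also treats all arrays as exchangeable, although the labels do not say what the repeat numbers share.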

How the results depend on the processing

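The fit without repeat 3 of 0 to 2 h and the fit of all probe sets were chosen after seeing the data. So were the settings for 6 h against 1 h, for the fixed lists at 0.5 h, and for the added lists and their genes. The settings for DOF2.1 and LHW at the other times were also chosen then. Median centring turned the majority of calls from higher to lower from 2 h on, and at 6 h 544 of the 686 genes kept their call and direction. The median change of all genes at 6 h was then -0.11, against -0.03 as deposited and -0.02 after a second quantile normalization. That normalization kept a majority of rises from 3 h on, and at 2 h it gave 74 rises and 93 falls. The direction of the majority thus depended on the normalization. In the settings other than single arrays left out, 125 values of single genes and 14 of lists lost their call in the same direction, 6 of single genes lost it and turned direction, and 15 and 11 gained one; with single arrays left out, 346 and 18 lost it and 8 and 19 gained one. The settings other than single arrays left out include the fit against 0.5 h, which is another comparison. Where no construction explains a change, the cause was not tested.

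A log2 change of at least 1, a stricter rule, left 9, 15, 40, 82, 78, 85 and 127 genes at 0.5, 1, 2, 3, 4, 5 and 6 h and 30 in late against early. Fits of the 6 arrays of both times hold fewer arrays and take the spread from those alone. They gave 0, 2, 8, 41, 69, 101 and 197 in the same order. The count of 0 at 0.5 h stands beside 905 genes at an unadjusted p under 0.05 in that limma fit. The fit of all arrays had 37 called genes there and 1264 at an unadjusted p under 0.05. With 0.5 h as the reference, 3, 54, 244, 210, 297 and 309 genes were called at 1, 2, 3, 4, 5 and 6 h. Against that reference AT1G20530 at 1 h was -0.21, SACL1 at 6 h -0.059, and SACL2 -0.17, -0.22, -0.35 and -0.10 at 3, 4, 5 and 6 h, since these genes were already higher at 0.5 h.

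Array weights ran from 0.619 to 0.88 for the 0 h arrays and from 1.06 to 1.43 for the 6 h arrays. They gave 23 genes at 0.5 h and 51 at 1 h. An intensity trend with robust spread gave 421 genes between 6 h and 1 h. All 38408 probe sets by ID gave 56, 140, 286, 921, 724 and 885 at 0.5, 1, 2, 3, 4 and 5 h, 2064 in late against early and 1163 in the F test. Without repeat 3 of 0 to 2 h the counts were 1325, 1075, 1091 and 1204 at 3, 4, 5 and 6 h and 501 between 6 h and 1 h, and 43 of the 78 genes of 1 h and 586 of the 686 of 6 h kept their call. With an estimated correlation 1 list was called at 6 h and 1 in late against early, and with the brightest probe set 1 list at 1 h.

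Arrays of the same repeat number shared some variation. After the mean of each time was taken off, 21 of 24 arrays correlated best with their own number. The mean correlation was 0.0484 for the same number and -0.0242 for other numbers. It was weak against 0 h, where 5 of 21 same-number correlations were over 0.1. These were repeat 3 at 0.5, 1, 2 and 3 h (0.181, 0.201, 0.223 and 0.12) and repeat 1 at 2 h (0.121), so the sharing lay mostly in repeat 3. The labels do not say what the numbers share, and the main fit held no block. With the replicate number as a block, fewer genes were called at 0.5 h (29) and more at every later time. The counts were 98, 224, 834, 728, 790 and 903 at 1, 2, 3, 4, 5 and 6 h. They were 1433 in late against early, 978 in the F test and 445 between 6 h and 1 h. Of the 686 genes of 6 h, 677 kept their call.

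Leaving out 1 array at a time gave 17 to 64 genes at 0.5 h, 43 to 124 at 1 h, 103 to 275 at 2 h, 195 to 1174 at 3 h, 190 to 996 at 4 h, 220 to 1023 at 5 h, 317 to 1129 at 6 h and 114 to 283 between 6 h and 1 h. It gave 838 to 1325 in late against early, 547 to 916 in the F test, and 1 to 3 lists at 1 h, 4 at 6 h and 2 to 3 in late against early. Of the 686 genes of 6 h, 21 lay in the lowest 25% of mean signal. Without that part 3 lists were called at 6 h and 2 in late against early, against 4 and 3: the TMO5/LHW module at 6 h (adjusted p = 0.0532) and, late against early, the type-A response regulators (0.106) and the added xyloglucan endotransglucosylases (0.0855) lost their call. No detection calls were used.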

Other observations

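The genes and lists of this part were picked out after their values were seen, among 21 lists composed from the annotated genes; the alternatives for them and the tests of other lists were likewise added, as was the value for neighbours that fell, and the tests of neighbours that rose were chosen before their results were seen. Of 20 stress and touch response genes, 4 fell and 1 rose at 6 h by limma, and the list lay lower in camera (mean change -0.41, adjusted p = 0.00123, and adjusted p = 0.335 with an estimated correlation). ORA47, an AP2/ERF gene, fell by 1.63, PUB24, a ubiquitin ligase gene, fell by 0.97, WRKY22 fell by 0.93 and PUB22 fell by 0.54, while BIK1, a receptor-like kinase gene, rose by 0.67. Without single arrays these calls were lost for PUB22 (any but array 2 of 6 h, adjusted p from 0.0523 to 0.103), BIK1 (any but array 3 of 0 h, 0.0791 to 0.209), WRKY22 (array 1 of 0 h and each 6 h array, 0.0509 to 0.121), PUB24 (array 1 of 0 h, array 3 of 6 h, 0.105 and 0.109) and ORA47 (array 1 of 0 h, 0.0783), and over all alternatives the adjusted p of the 5 ran from 5.35e-04, for BIK1, to 0.219, for ORA47. Of 11 genes of the iron list, 1 rose at 6 h, ZIP6, a metal transporter gene, by 0.78, and the list lay higher (mean change 0.28, adjusted p = 0.00695, and adjusted p = 0.335 with an estimated correlation). The gene listed there as FRO1 was matched by symbol to AT5G67590, which is not the ferric reductase, and its change was 0.15. The call of ZIP6 was lost without array 1 or 2 of 0 h (adjusted p = 0.208 and 0.0828) and array 2 or 3 of 6 h (0.0615 and 0.188), with 0.00631 to 0.271 over all alternatives.

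Among 14 SWEET sugar transporter genes, SWEET16, SWEET17 and SWEET2 rose at 6 h by 1.21, 0.80 and 0.64, and the list as a whole was not called (adjusted p = 0.444). SWEET17 was called in all 15 alternatives (adjusted p from 9.9e-04 to 0.0323), while SWEET16 lost its call without array 1 of 0 h (adjusted p = 0.0722, and 9.31e-04 to 0.218 over all alternatives) and SWEET2 without array 1 or 2 of 0 h (0.111 and 0.0829) and array 1 or 2 of 6 h (0.0717 and 0.134, and 0.0038 to 0.134 over all alternatives). Among 9 xyloglucan endotransglucosylase genes, 3 were higher late than early, among them XTH26 by 1.05 and XTH32 by 0.61, and the list lay higher (adjusted p = 0.0323, and adjusted p = 0.191 with an estimated correlation). That call was lost without the dimmest 25% of genes (adjusted p = 0.0855) and without array 1 of 1 h (adjusted p = 0.0513), array 1 of 2 h (0.0519) and array 3 of 4 h (0.0581), with 0.0115 to 0.191 over all alternatives. The lists of 18 cell division genes, 13 replication and histone genes and 15 ribosomal protein genes had mean changes of 0.03, 0.06 and -0.07 at 6 h and were not called.

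Genes called at 6 h lay next to each other among the genes tested more often than in random sets. Among 410 genes that rose there were 18 adjacent pairs, against a mean of 10.2 and a highest value of 25 in 10000 random sets (permutation p = 0.0162, one-sided), and among 271 that fell there were 10, against a mean of 4.46 (permutation p = 0.016, one-sided). The count of 18 for genes that rose passed the bound set beforehand, with 17 as the upper bound of the random sets. Those sets were drawn from all placed genes without matching on signal. Of the 686 genes called at 6 h, 21 lay in the lowest 25% of mean signal. The test therefore cannot exclude chance placement among genes of like signal. Shared hybridization of similar copies may add to the count, but which pairs are similar copies was not scored. The residual correlation ran from -0.338 for AT1G07550 and AT1G07560 to 0.714 for AT3G51330 and AT3G51340. It was 0.713 for AT3G45700 and AT3G45710 and -0.188 for AT5G51780 and AT5G51790. Over the 18 pairs it had a median of 0.229, with quartiles of -0.07 and 0.56, against 0.207 in 1000 random pairs of risers, and the sources cannot be told apart without probe sequences.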
